A study of Homo sapiens with 2 samples.

How the data were processed

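Chromatin immunoprecipitation with promoter microarrays (ChIP on chip) was used on 1 cell line. Per the labels, each of the 2 arrays carried DNA precipitated with the anti-p53 antibody DO-1 in the Cy5 channel and DNA precipitated with non-specific IgG in the Cy3 channel, both from PLC/PRF/5 cells. The dyes in the labels give the direction of every ratio, and a ratio above 0 on the log2 scale means more Cy5 (p53 ChIP) than Cy3 (IgG). The file headers name 2 array designs, 014706 and 014707. They hold 237210 and 237201 probes, with 0 probes in common, so each probe was measured on 1 array only. There were no dye-swapped arrays, and a difference between the dyes cannot be told apart from a difference between the antibodies.

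Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.3.1 and the protocol ChIP_107_Sep09, and the deposited scanner files hold the spot intensities. The processed signal intensities were background-subtracted, detrended over the array surface and scaled between dyes by 1 linear factor per channel, per the file headers. The scanner files of the authors also hold the log10 ratio of Cy5 over Cy3 and an error-model p-value for each spot, which compares 2 channels of 1 spot and covers no biological spread. In the deposited file of array 2 these columns are rounded to 3 significant digits. The processed signals of array 2, from which the ratios here were taken, also had at most 3 significant digits at the regions named below. The flags that mark a spot as well above background or as an outlier are another kind of column, a score of 0 or 1 written by the scanner software and deposited by the authors. The log2 values in the series' value tables deposited by the authors matched the log2 ratio of median signal minus local background median, Cy5 over Cy3, with r = 1 on both arrays, and no value differed by more than 5.65e-07. Their medians were -0.11 and -0.24, so they were not centred, and 370 and 314 probes had no value. Further steps of the authors are not given in the sources used here.

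The ratio used here was log2 of the processed Cy5 signal over the processed Cy3 signal, less the median of the array (0.41 and 0.32), with no loess or quantile step. Control spots, 10 outlier probes and probes well above background in neither channel (8.34% and 8.22%) were left out, which kept 217425 and 217706 probes. No spot was saturated. A window was 3 neighbouring kept probes with gaps of at most 1000 bp, and its score was their mean log2 ratio. Windows with a score of at least 1 and all 3 probes above 0 were merged where they shared a probe, and are called enriched regions. Mirror regions are the same with the signs turned, that is, higher in IgG. Mirror regions count how many regions a signal that is symmetric about 0 gives. Centring on the median puts as many probes above 0 as below, so it moves the counts of enriched and mirror regions towards each other, and all folds are relative to the array's median. Runs of probes with gaps of at most 1000 bp are called tiled stretches, and a stretch stands in for a promoter, a choice also made after the files were seen. The rule set before the data were examined was written for genes; applied to regions, a change made after the files were seen, it took the 12 highest-scoring enriched and the 3 highest-scoring mirror regions of each array. A region takes the score and the fold of its highest-scoring window of 3 probes, not of all its probes. Where a probe of the dimmer channel was not well above background, the score is a bound: that signal was raised to the lowest signal among probes well above background in its channel, and the fold is written as "at least".

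No test across replicates was possible, because each probe has 1 value. The number of arrays limits the precision, no p-value is given across probes, and the intervals on shares of regions are exact (Clopper-Pearson) 95% intervals that treat regions as independent and cover counting error only. The spread of repeated control spots gives the technical error of bright spots only. Standard errors of chromosome medians come from 200 bootstrap draws of whole stretches, and their SD after probe-length centring was compared with 10000 random assignments of stretches to chromosomes (one-sided permutation test, also added after the data were seen). The region caller was tested on simulated ratios at the real probe positions. Of 50 planted regions per size on a flat background, 100% were found with exact bounds at each size on both arrays. That background held no noise, so it cannot show how exact the bounds are on real ratios. Noise was also simulated with the arrays' own SD and a correlation between neighbours that decays over 182 and 181 bp. On it, a planted effect of 2 on the log2 scale was recovered at 80% (array 1) and 84% (array 2) of the planted sites. With nothing planted, 41% and 41.5% of all planted sites were called. On noise, bounds were exact for 12% of the planted regions of that effect on both arrays, and for 4% to 26% over all sizes. The bounds printed for regions are those of the caller and need not be those of a signal.

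The genome build behind the probe coordinates is not given in the sources used here, and the positions are printed as the files give them. As a check against GRCh38.p14, 13.6% of the stretches of at least 4000 bp held an end of a protein-coding gene of that assembly, and 10.8% to 12.9% did after shifts of 500000 or 1000000 bp either way, so the coordinates were not read as GRCh38. Gene names, probe sequences and distances to transcription starts were therefore not analysed here. The gene lists, the named genes and the sequence motifs fixed before the data were examined were not tested for the same reason. Regions are named by position, and the middle of a stretch was used in place of the transcription start. Chromosome Y is in the totals and is not described by chromosome.

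Alternatives set before the data were examined were normexp background correction (limma 3.58.1, R 4.3.3, offset 50, on median signals), lowess within the array (fraction 0.3), centring in 20 intensity bins, a stricter and no filter on dim probes, windows of 5 probes, thresholds of 0.6 and 1.5, a requirement on the error-model p-value (at most 0.01 in at least 2 of 3 probes), the value tables, and each array alone. Centring within each probe length, raising dim spots to a floor, leaving the ratios or the value tables uncentred, the noise simulation, and the analyses by chromosome, probe length, long regions and position in a stretch were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.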

Results

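The design asks which promoter DNA is bound by p53 with the R249S substitution, an arginine-to-serine change in the DNA-binding domain, in PLC/PRF/5 cells, a human hepatoma line that carries it. DO-1, the antibody used, recognises the amino-terminal part of human p53, and the IgG precipitate measures the background. The promoter probes were split over 2 arrays. Array 1 held 237210 probes on 10 chromosomes (1 to 10) and array 2 held 237201 probes on 15 chromosomes (10 to 22, X and Y), and each array was hybridised once. Probes lay in 29762 tiled stretches, with a median spacing of 177 bp on array 1 and 178 bp on array 2. There were no replicates of any probe, so no value below has a replicate check.

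The p53 ChIP channel passed its detection floor at more probes than the IgG channel, but the floors were unlike on the processed scale. That scale includes the factor applied to each dye, so these floors do not compare the channels' intensities before scaling. The lowest processed signal counted as well above background was 112 (array 1) and 118 (array 2) in Cy5. In Cy3 it was 314 on both arrays. The Cy5 (p53) signal was well above background at 88.8% of the probes of array 1 and 89.2% of array 2, and the Cy3 (IgG) signal at 67.5% and 68.0%. On array 1, 57411 probes were well above background in Cy5 alone and 6894 in Cy3 alone; on array 2, the numbers were 56408 and 6077. The IgG signal was concentrated in fewer probes: the brightest 1% held 17.7% (array 1) and 17.3% (array 2) of the background-subtracted IgG signal, against 10.8% and 10.9% of the p53 signal. Across probes, the log2 signals of the 2 channels correlated with r = 0.49 and r = 0.50, where probes are not independent replicates.

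The ratio of p53 ChIP to IgG varied widely in both directions about the array median. Its SD over probes was 2.22 on the log2 scale on array 1 and 2.13 on array 2. Control probes spotted at least 12 times on the array and well above background had median SDs of 0.12 (19 probes) and 0.09 (20 probes), which is the error of bright spots only; the error of promoter probes, many of them dim in one channel, was not measured. Of the kept probes, after centring on the array's median, 34.5% on array 1 and 33.7% on array 2 were at least 2-fold higher in the p53 ChIP, and 33.5% and 31.0% were at least 2-fold higher in IgG. The tails were less even. A log2 ratio of at least 3 was reached by 6.68% and 7.10% of kept probes towards the p53 ChIP. Towards IgG, 11.5% and 9.62% reached that size.

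With ratios centred on the median of each array, promoter regions higher in the p53 ChIP were about as many as regions higher in IgG, a balance that the centring itself favours. At a 3-probe score of at least 1 on the log2 scale, array 1 had 14076 enriched and 13818 mirror regions, and array 2 had 13749 and 13056. The enriched share was 50.5% on array 1 (95% interval 49.9% to 51.1%) and 51.3% on array 2 (50.7% to 51.9%). Over both arrays it was 50.9%, and it was 49.9% with ratios centred within each probe length, a setting added after the data were seen. Without centring, also a setting added afterwards, there were 16776 enriched and 10896 mirror regions on array 1 and 16064 and 10389 on array 2, an enriched share of 60.7% over both. Noise was simulated with the SD and neighbour correlation of the measured ratios. It gave 13514 enriched and 13616 mirror regions at the positions of array 1 and 13405 and 13396 at those of array 2. Any binding in the measured ratios is part of that SD and correlation. Similar counts therefore cannot show whether binding is present. At a score of at least 3, mirror regions outnumbered enriched regions, with 4149 against 1610 on array 1 and 3325 against 1815 on array 2. The simulated noise gave 3204 mirror and 3133 enriched regions at that score on array 1 and 2760 and 2711 on array 2, so its counts, close to the measured ones at a score of 1, differed from them at 3. With probes well above background in both channels only, the measured numbers at 3 were 1445 mirror against 1450 enriched regions and 1239 against 1222. Without centring, enriched regions were the more numerous at 3, with 2627 mirror against 3692 enriched regions and 2284 against 3311. Relative to enriched regions, mirror regions were more in excess with ratios centred within probe length (4963 against 1005 and 4211 against 913). The same held with normexp background correction (218 against 45 and 238 against 33). In the remaining settings compared, mirror regions were the more numerous at 3 on both arrays.

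**Figure D1:**
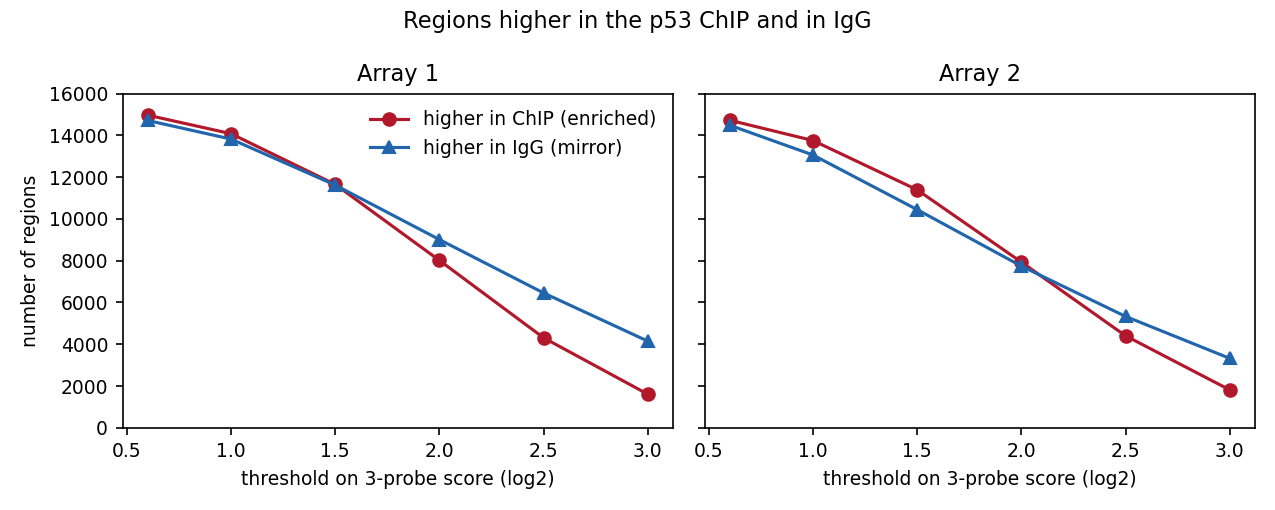
Number of regions (y axis) at each threshold on the 3-probe score (x axis, log2 scale), for regions higher in the p53 ChIP (circles) and in IgG (triangles) after centring on the array's median, 1 panel per array. The lines lie close together at low thresholds, with the p53 side ahead at 1.5 on array 2 (11389 against 10442), and at 3 the IgG side is higher on both arrays (4149 against 1610 and 3325 against 1815).

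Enriched and mirror regions had similar median widths. The median width was 653 bp (enriched) and 639 bp (mirror) on array 1, and 665 bp and 634 bp on array 2, and each kind covered a median of 4 probes. Regions of at least 1500 bp made up 9.38% of enriched and 8.63% of mirror regions on array 1, and 10.1% and 7.50% on array 2. Of 23472 stretches with at least 1 window, 67.6% held an enriched region, 65.6% held a mirror region and 47.1% held both; whether the kinds share stretches beyond chance was not tested. Among stretches with at least 20 windows, 93.0% on array 1 and 92.1% on array 2 held an enriched region, and 93.8% and 91.3% held a mirror region.

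The ratio was shared between probes only over short distances. Probes 100 to 150 bp apart correlated with r = 0.52 on both arrays, probes 300 to 500 bp apart with r = 0.08 on both, and probes 500 to 1000 bp apart with r = -0.01 on array 1 and 0.02 on array 2. The same decay was present in each channel alone: at 100 to 150 bp, r was 0.39 and 0.36 for the p53 signal and 0.43 and 0.40 for the IgG signal. The p53 signal at a probe correlated with the IgG signal at the neighbour 100 to 150 bp away with r = 0.08 on array 1 and 0.07 on array 2. Left and right parts of the same stretch, kept 1000 bp apart, had mean ratios that correlated with r = 0.03 (4658 stretches) and 0.06 (4480 stretches). These are correlations across probes or stretches of 1 array.

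**Figure D2:**
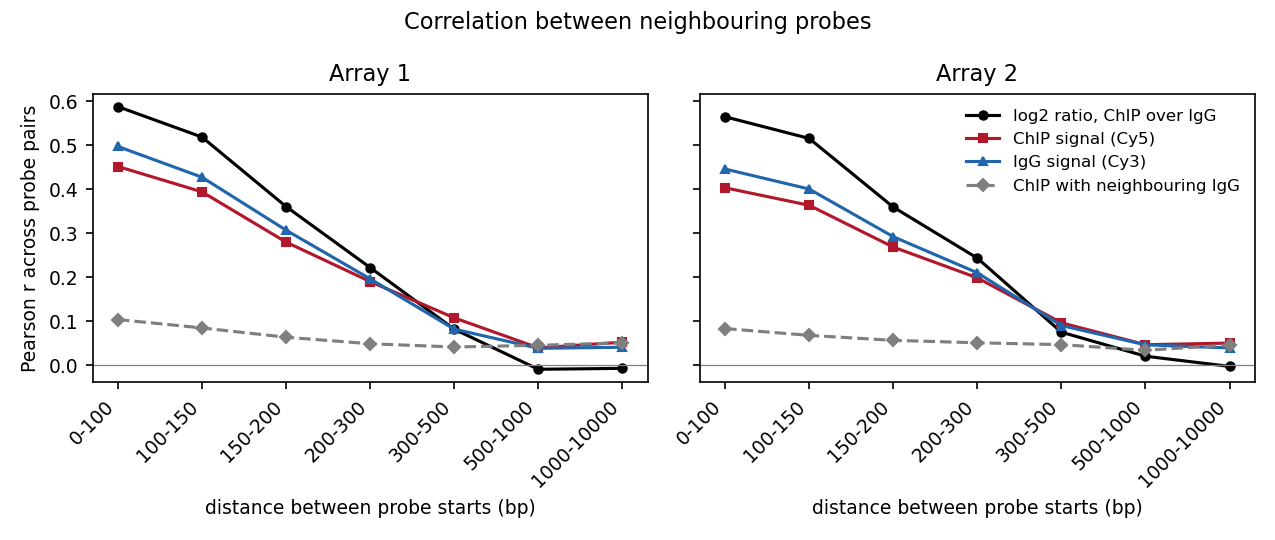
Pearson correlation across pairs of neighbouring probes (y axis) by the distance between their starts (x axis, bp), for the log2 ratio, each channel's log2 signal, and the p53 signal with the neighbouring IgG signal, 1 panel per array. At 100 to 150 bp the ratio correlates with r = 0.52 on both arrays, and the p53 signal with the neighbouring IgG signal at 0.08 and 0.07.

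The highest-scoring enriched regions of array 1 lay on 7 chromosomes and were 427 to 1126 bp wide. Their measured scores ran from 4.32 to 4.63 on the log2 scale, with SDs over the 3 probes of 0.21 to 1.53. All 12 held at least 1 spot whose IgG signal was not well above background, so each fold is a lower bound. Each fold is that of the best 3-probe window within the coordinates given, and other probes of the region can be lower. On chromosome 1, the region from 32785198 to 32785624 was at least 9.32-fold higher in the p53 ChIP, that from 194609044 to 194610169 at least 12.3-fold, and that from 224224448 to 224225301 at least 15.7-fold. The bounds were 7.07-fold at 116349530 to 116350315 and 14.7-fold at 190372110 to 190372799 on chromosome 3. They were 5.75-fold at 148630697 to 148631272 and 6.76-fold at 22889035 to 22889580 on chromosome 5, and 7.19-fold at 46246888 to 46247821 on chromosome 6. On chromosome 7 they were 16.1-fold at 129528814 to 129529326 and 12.2-fold at 147723744 to 147724175. The region at 22604265 to 22604942 on chromosome 8 had a bound of 18.2-fold, and that at 82907774 to 82908599 on chromosome 9 one of 9.86-fold.

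On array 2 the 12 highest-scoring enriched regions also lay on 7 chromosomes, were 267 to 1676 bp wide and had measured scores of 4.37 to 4.88. The SDs over the 3 probes were 0.27 to 1.82, and again all 12 held a dim IgG spot. Folds are again those of the best 3-probe window within each region. Chromosome 11 had the most probes (30075) and the most enriched regions (1832) of the chromosomes described on array 2, beside 1686 mirror regions. Of the 12 regions, 5 were on chromosome 11. They were at least 20.1-fold higher in the p53 ChIP at 7491064 to 7491330, 8.53-fold at 77578855 to 77579209, 21.1-fold at 118714196 to 118715598, 11.3-fold at 123030909 to 123031588 and 13.7-fold at 131288075 to 131289073. The bounds were 17.2-fold at 70514412 to 70515882 on chromosome 10, 10.2-fold at 56170048 to 56170762 on chromosome 12 and 8.16-fold at 34945271 to 34945800 on chromosome 14. They were 7.62-fold at 48256982 to 48258657 on chromosome 15, 11.6-fold at 16018609 to 16019749 and 7.31-fold at 32645041 to 32646418 on chromosome 22, and 6.42-fold at 54717620 to 54718323 on chromosome X.

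The 3 highest-scoring mirror regions of each array were on chromosomes 3 and 9 (array 1) and 10, 14 and X (array 2). Each fold below is that of the best 3-probe window within the region, not of all its probes. On array 1, IgG was higher by at least 113.0-fold at 50355563 to 50356459 on chromosome 3, by 118.2-fold at 112897874 to 112898261 on chromosome 9 and by at least 33.6-fold at 129984749 to 129985429 on chromosome 9. On array 2, it was higher by at least 46.7-fold at 23871686 to 23872210 on chromosome 14, by 107.1-fold at 127397981 to 127398250 on chromosome 10 and by 101.2-fold at 136371156 to 136372463 on chromosome X. The 3 folds written with "at least" rest on dim p53 spots. As every named enriched fold is also a lower bound, the sizes of the enriched and mirror folds cannot be ranked against each other.

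**Figure D3:**
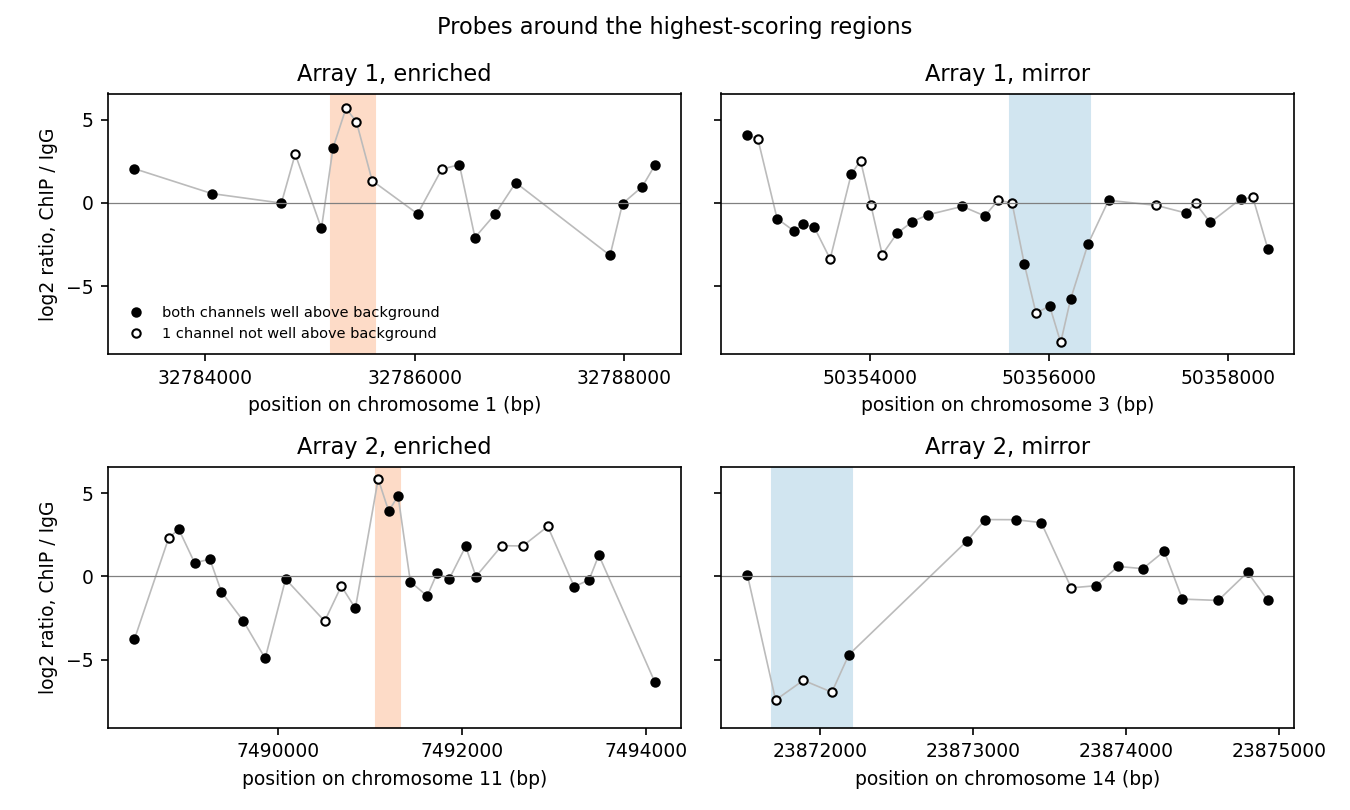
Log2 ratio of p53 ChIP over IgG (y axis) of each probe against its position (x axis, bp as the files give it) within 3000 bp of the highest-scoring enriched and mirror region of each array. Shading marks the region, filled points have both channels well above background and open points only 1; the shaded peaks span 427 bp and 267 bp (enriched) and 897 bp and 525 bp (mirror).

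The chromosomes with the highest and lowest median ratios differed by more than their bootstrap SEs. Among chromosomes 1 to 22 and X, the median was highest on chromosome 18 (0.35 ± 0.05, bootstrap SE, on the log2 scale) and on X (0.24 ± 0.04), and lowest on chromosome 22 (-0.28 ± 0.03) and chromosome 16 (-0.23 ± 0.03). On chromosome 18, 505 regions were enriched and 330 were mirror regions, an enriched share of 60.5% (57.1% to 63.8%). The share was 44.3% (42.0% to 46.5%) on chromosome 16 and 45.2% (43.3% to 47.1%) on chromosome 19. On array 1 the medians ran from -0.15 (chromosome 9) to 0.10 (chromosome 5). The share of probes of 45 bases, the shortest on the arrays, varied with these medians: across chromosomes, which are not replicates, r was -0.86 (rho -0.81) on array 1 with 10 chromosomes and -0.96 (rho -0.96) on array 2 with 14 chromosomes. With ratios centred within each probe length, the SD of the chromosome medians was 0.04 on both arrays, against 0.08 on array 1 and 0.18 on array 2 as measured.

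**Figure D4:**
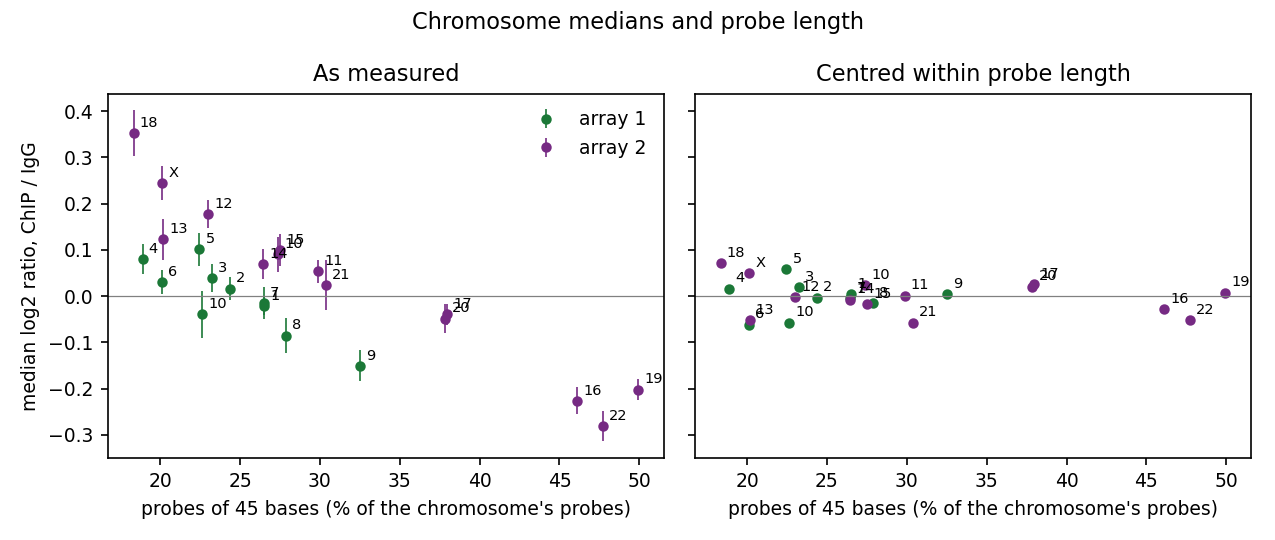
Median log2 ratio of each chromosome (y axis; bars are bootstrap SEs in the left panel) against its share of 45-base probes (x axis, %), as measured and after centring within probe length, for array 1 and array 2. As measured, chromosome 18 (0.35) and chromosome 22 (-0.28) are the extremes; after centring, medians lie between -0.06 and 0.07.

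The ratio was lowest at the shortest probes. The median was -0.65 on the log2 scale for 45-base probes and 0.46 for 60-base probes on array 1, and -0.51 and 0.64 on array 2. Most of the rise lay below 50 bases, where the median was 0.36 on array 1 and 0.51 on array 2. Beyond that length the medians went up and down, with 0.21 and 0.24 at 51 bases. Stretches of 5000 to 9000 bp (3743 on array 1 and 3552 on array 2) were cut into 5 parts from the middle outwards, and each mean below has an SE of 0.02 over stretches. From the innermost to the outermost part, the mean ratio was -0.14, -0.17, -0.10, -0.07 and -0.03 on array 1, and -0.02, -0.12, -0.06, 0.07 and 0.04 on array 2. With ratios centred within probe length, it was -0.26, -0.21, -0.18, -0.26 and -0.28 on array 1, and -0.18, -0.22, -0.19, -0.16 and -0.25 on array 2. In none of these 4 profiles was the innermost part the highest. On array 2 after probe-length centring, though, the innermost part (-0.18) and the highest (-0.16) were too close for their SEs to resolve. How near the middle of a stretch lies to a transcription start is not known.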

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

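Probe-length centring, the floor for dim spots, and ratios or value tables left uncentred were chosen after the data were seen, and the other alternatives before. Each count is over both arrays. As reported, there were 27825 enriched regions, 26874 mirror regions and 15856 stretches with an enriched region, and the enriched share was 50.9% (95% interval 50.4% to 51.3%). Windows of 5 probes gave 10085 enriched and 10075 mirror regions, 8065 stretches with an enriched region and a share of 50.02%, with array 1 on the IgG side (49.6%). Requiring both channels well above background gave 17485 and 16713 regions. Normexp gave 18639 enriched and 14811 mirror regions, a share of 55.7%. The share was 50.2% with centring in intensity bins, 50.4% at a threshold of 0.6, 52.98% with the error-model requirement and 51.4% with dim spots raised to a floor. It was 60.7% with ratios not centred (32840 enriched and 21285 mirror regions), so the balance depends on where the zero is set. It was 51.4% with the value tables not centred, with array 1 at 54.0% and array 2 on the IgG side at 48.5%. It was 49.9% with ratios centred within probe length, within counting error of equal numbers: array 1 turned to the IgG side (49.4%) and array 2 did not (50.3%). The cause of the other changes was not tested, except that fewer probes enter under the stricter filter. With each array alone, which drops the other's probes, enriched regions numbered 13749 to 14076, mirror regions 13056 to 13818, stretches with an enriched region 7918 to 7938, and the share was 50.5% to 51.3%. The correlation of probes 100 to 150 bp apart stayed between 0.49 and 0.55 under the alternatives that change the ratios or the probes kept. The intended GC correction and the comparisons on gene lists, motifs and distances to transcription starts were not run, since they need sequences or gene positions. Normexp was run on median signals. No paired analysis was possible because there is 1 group and no probe is on both arrays. The median background-subtracted signal was lower for IgG (33.6 and 35.2) than for the p53 ChIP (75.5 and 72.5).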

Other observations

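The tests of spot noise, of p53 binding and of separately sampled fragments, the final criterion for base composition, the centring within probe length, the permutation of stretches and the account of long regions were chosen after related results were seen; the tests of a probe property and of the length make-up of chromosomes had their outcomes written down before they were run.

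Enriched regions of at least 1500 bp outnumbered mirror regions of that length in the main setting, but the size and the direction of the difference depended on the processing. Regions of at least 1500 bp numbered 1321 enriched against 1192 mirror on array 1 and 1393 against 979 on array 2, where simulated noise gave 1149 against 1158 and 1153 against 1116. With ratios centred within probe length, the counts were 1029 against 1049 and 984 against 920, and with centring in intensity bins 1163 against 1181 and 1245 against 1031. The excess was larger with normexp (523 against 288 and 500 against 281) and with both channels well above background (1069 against 815 and 1099 against 712). It was largest without centring on the array's median (2112 against 610 and 2055 against 548). Over the main setting and the 10 alternatives compared, the ratio of enriched to mirror counts ran from 0.98 to 3.46 on array 1 and from 0.92 to 3.75 on array 2. Counted by probes, the main setting differed between arrays. Regions of at least 15 probes numbered 17 enriched against 35 mirror on array 1 and 22 against 12 on array 2. Simulated noise gave 18 against 9 and 14 against 24. These counts were 15 against 28 and 18 against 14 with intensity bins, and 53 against 8 and 68 against 3 without centring. The longest enriched region, singled out after its values were seen, was on array 2, on chromosome 17 from 38203024 to 38208437. All 25 of its kept probes were higher in the p53 ChIP, with a mean of 2.60 ± 0.95 (SD over 25 probes) on the log2 scale. A single simulation of noise on array 2 reached 23 probes in a region, and mirror regions there reached 21. With no filter on dim probes, mirror regions reached 37 probes and enriched regions 22. So 25 is little beyond the 23 of that simulation, which was run once and gives no spread. Its noise takes its SD and correlation from the measured ratios, so it cannot show whether the region reflects binding. All 25 probes were above 0 also with lowess, normexp, intensity bins, the value table, probe-length centring and the floor for dim spots, with means of 1.53 to 2.58. With probes well above background in both channels, 13 probes were left, all above 0; with no filter, 25 of 26 were. On array 1 the longest enriched region, also singled out afterwards, was on chromosome 5 from 126882180 to 126887068. It had 11 probes with a mean of 2.29 ± 1.09. Of these, 9 were above 0 with normexp, the value table and the floor for dim spots. With probes well above background in both channels, only 3 probes were left, all above 0. The simulation of array 1 reached 21 probes.

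After centring on each array's median, nearly as many promoter regions were higher in IgG as in the p53 ChIP. The tables argue against independent noise of single spots, since probes 100 to 150 bp apart correlated with r of at least 0.515 on both arrays. Whether p53 binding is the source of most regions cannot be decided from the counts, which restate the pattern and move with the zero. Mirror regions were at least 0.647 times as many as enriched ones on both arrays. This held with the zero at the array's median, at the scanner software's dye scaling and with no dye scaling. It met the outcome set for excluding binding, but that outcome was written after related results were seen. The correlation between probes 100 to 150 bp apart in 1 channel does not depend on the zero. It was no lower for the IgG signal (r = 0.43 and 0.40) than for the p53 signal (0.39 and 0.36). Correlated neighbours were therefore not particular to the p53 precipitate. A candidate explanation is that few DNA fragments were sampled and amplified separately in each precipitate. The IgG signal correlated with the neighbouring p53 signal at no more than 0.0848, which met a bound set after related results were seen. Precipitates that differ for another reason, p53 binding included, can also give a low value, so the test cannot favour this explanation. A first test, on the IgG signal left after regression on the p53 signal (r = 0.48 and 0.47), also met its bound. It was replaced after its result was seen, because that remainder carries p53 signal. Binding of p53, at some or at most regions, and dye differences stay open, since the zero is not fixed independently of the scaling. Adding 0.7 to the centred log2 ratios, more than any scaling tried, would bring mirror regions to 0.476 and 0.411 times the enriched ones.

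The ratio was lower at 45-base than at 60-base probes, with mean differences of -0.70 on array 1 and -0.74 on array 2 on the log2 scale. The IgG signal was well above background at 78.4% of 45-base and 61.2% of 60-base probes on array 1, and at 79.6% and 58.9% on array 2. For the p53 signal the values were 90.4% and 87.1%, and 92.3% and 86.3%. Whether dim IgG spots bear on the difference was not tested. Between a 45-base and a 60-base probe at most 150 bp apart, the mean difference was -0.54 ± 0.04 (SE over 2738 stretches) and -0.56 ± 0.04 (2720 stretches), at least 0.753 of the overall difference, which is consistent with a property of the probe itself. Base composition of the surrounding DNA predicted that 60-base probes between 45-base probes would differ from those between 60-base probes by -0.3 or less; they differed by 0.145 ± 0.10 (SE, 638 probes) and 0.08 ± 0.08 (773 probes), which argues against it. The outcome written beforehand for excluding it, within 0.1 of 0 on both arrays, was missed on array 1, and by that criterion alone the test was undecided; the criterion used instead, more than 2 SE above -0.3 on both arrays, was added after the values were seen. No biological explanation was tested.

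Chromosome medians of the ratio differed, from -0.28 to 0.35. Centring within probe length lowered their SD by 53.3% on array 1 and 78.7% on array 2 (the smaller fall is 0.533 as a fraction), which is consistent with the make-up of the probes by length as a source of most of the differences. What is left, an SD of 0.04 on each array, had a permutation p of 0.0944 on array 1 and 0.0273 on array 2 against stretches dealt out to chromosomes at random (0.0944 and 0.0546 after Benjamini-Hochberg adjustment over these 2 tests). Differences between chromosomes beyond probe length therefore stay open. No biological explanation was tested.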
